A study of Mus musculus with 36 samples.

How the data were processed

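RNA was taken from cultured mouse lung pericyte-like cells after exposure to media only, uninjured BALF or injured BALF for 6 or 24 h, per the labels' protocols, and libraries were made with a stranded mRNA kit. The authors deposited a table of counts per gene as whole numbers, with 48795 Ensembl gene identifiers and 36 libraries. STAR 2.5.2b, RSEM 1.2.31 and DESeq2 are named, per the submitters' processing notes, together with the GRCm38 build, and the role of each is not given in the sources used here. The counts may therefore be rounded RSEM estimates, in which a read that fits several genes is shared among them. Such sharing makes the values of near-identical gene copies uncertain.

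Identifiers were matched to the GENCODE M21 annotation of GRCm38 for symbols and positions, and 48349 of them (99.1%) matched; the rest held at most 0.051% of the counts of any library. Mitochondrial genes took 1.20 to 3.87% and the 10 most abundant genes 7.05 to 12.6% of a library's counts. Both highest values are those of female media 24 h replicate 1, and the other 35 libraries held at most 2.05% and 10.9%. Libraries were mapped to columns by their titles, also for the 3 female uninjured BALF 24 h libraries, whose descriptions carry 25 where those of the male ones carry 24. The comparisons, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined.

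Differences were tested with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test and TMM scaling (factors 0.874 to 1.092), on all 36 libraries in 12 groups of treatment, sex and time, with 24 residual degrees of freedom. Genes with too few counts were removed by edgeR's expression filter, which left 15901. The common biological coefficient of variation was 22.5%. A treatment effect was the mean of the female and male effects. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called changed. Values after ± on log2 fold changes are approximate standard errors, taken as the fold change divided by the square root of the test's F statistic.

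Named genes are the 10 with the largest rise and fall in injured against uninjured BALF at each time and the 5 in other comparisons, among called genes of at least 2 average log2 CPM and with the same direction in both sexes. A fixed set of marker genes and the 4 lowest p-values of each list were named too. The 35 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry. A list with fewer than 3 measured genes was not tested, which left out lymphocyte markers (2 measured) and erythroid markers (0).

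The gene tests and list tests were tested on simulated counts for injured against uninjured BALF at 6 h (15901 genes). Every library was given the real means of uninjured BALF at 6 h and its own library size. Changed genes were drawn from those above 1 CPM in uninjured BALF at 6 h, so recovery below that was not tested. Of 50 genes changed by each size, edgeR recovered 29 at 1.5-fold, 43 at 2-fold, 48 at 4-fold and 49 at 8-fold, with 12 false calls. DESeq2 1.42.0 recovered 35, 43, 49 and 50, with 24 false calls. Of 30 unchanged gene sets camera called 0 and fry 1. Genes and libraries were simulated as independent. False calls for sets of correlated genes, or from the closeness of libraries numbered 1 and 2, were therefore not tested.

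Alternatives were DESeq2, 2 other scalings, 2 other low-count filters, stricter thresholds, a block of replicate number, fitting only the groups compared, ignoring sex, and leaving out each library, each replicate number and the 4 libraries whose description numbers differ. A term for those 4 libraries, the sum of libraries 1 and 2, and that sum with numbers 1 and 3 exchanged in female uninjured BALF at 24 h were added after the data were examined. The count of 0 in a group allows up to 3 counts, and intervals and floors cover counting error only. Reads were not analysed here.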

Results

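Gene expression was measured by stranded mRNA sequencing in mouse lung pericyte-like cells, cells resembling those that wrap small vessels, grown out of lung digests. Cells carrying CD31 (endothelial), CD45 (leukocyte) or CD326 (epithelial) were removed, and cells carrying PDGFRβ, a receptor of pericytes and fibroblasts, were kept and cultured. They were then exposed for 6 or 24 h to media only, to bronchoalveolar lavage fluid (BALF) from uninjured lungs, or to BALF from injured lungs, each fluid mixed with an equal volume of reduced-serum medium (buffered saline took the place of BALF in media only). The kind of injury is not given in the labels. Each treatment and time had 3 female and 3 male libraries, which made 12 groups and 36 libraries, and n = 6 for every treatment at every time. Total counts per library ran from 17134840 to 35991683. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples only.

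Every library carried the transcripts its sex label predicts: Xist, transcribed from the inactive X chromosome, lay at 342 to 776 CPM (counts scaled to a common library total) in the 18 female libraries and at 0.167 or less in the 18 male ones. Pdgfrb, the gene of the selection marker, was read at 256 to 791 CPM over all libraries. Summed pericyte markers reached 2100 ± 223 CPM in media at 6 h (mean ± SD, n = 6) and lung fibroblast markers 1170 ± 60.1. The pericyte list includes Pdgfrb, on which the cells were selected, at 599 to 791 CPM in these libraries. The 2 sums therefore do not tell pericytes from fibroblasts. Endothelial markers reached 159 ± 44.2, mesothelial markers 53.8 ± 29.0, macrophage markers 64.7 ± 23.7 and neutrophil markers 1.81 ± 1.08. Endothelial and macrophage transcripts were therefore present at a low level although cells with CD31 and CD45 had been removed. 4 libraries have description numbers that begin differently from the rest: male uninjured BALF 24 h replicate 3, female media 24 h replicate 2, male media 24 h replicate 3 and male media 6 h replicate 3. None of the 4 is of injured BALF, so what sets them apart is partly mixed with treatment. In these 4, Lyz2, a macrophage gene, lay at 5.42 to 9.45 CPM, against 21.8 to 61.1 in the other 32, and Pecam1, an endothelial gene, at 0.709 to 2.16 CPM against 5.60 to 35.3. Libraries numbered 1 and 2 were the closest pair in 10 of 12 groups, at a biological coefficient of variation of 6.3 to 12.7% there and a median of 8.3% over all groups, while the median between numbers 1 and 3 was 24.3% and that between 2 and 3 was 23.8%. Numbers 2 and 3 were the closest pair in female uninjured BALF at 24 h (15.7%, against 34.7% between 1 and 2) and in female media at 24 h (26.1% against 36.8%). Where numbers 1 and 2 share an origin, n is smaller than 6, and each count of changed genes is given also with those 2 libraries summed to 1, a choice made after seeing their distance. Female media at 24 h was summed in the same way although its numbers 1 and 2 were not close, so that sum may join separate libraries.

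**Figure D1:**
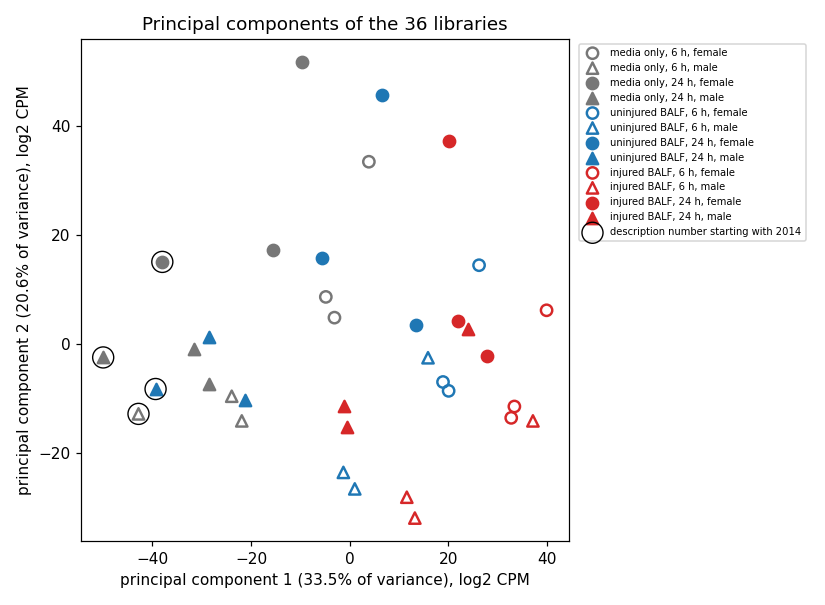
First and second principal components of log2 CPM over the 36 libraries, which hold 33.5% and 20.6% of the variance; colour marks the treatment, filled symbols 24 h, open symbols 6 h, circles female and triangles male. Large rings mark the 4 libraries with the differing description numbers.

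The comparison of injured with uninjured BALF asks what the cells do in fluid from an injured lung beyond what they do in lavage fluid as such. At 6 h, genes of leukocyte recruitment were among those that rose most. Cxcl2, a chemokine that draws neutrophils, rose from 1.75 ± 0.951 to 66.0 ± 24.0 CPM (mean ± SD, n = 6 each), a log2 fold change of 5.32 ± 0.45 (± standard error; edgeR adjusted p = 1.4e-08). Ccl2, which draws monocytes, rose from 231 ± 217 to 1677 ± 296 CPM, by 3.02 ± 0.39, with 672 CPM in female uninjured BALF replicate 3 and 116 to 171 in the other 5 uninjured libraries. Nos2, the inducible nitric oxide synthase, rose from 0.286 ± 0.258 to 26.0 ± 14.1 CPM. Vcam1, an adhesion molecule that leukocytes bind, rose by 1.68 ± 0.15 and Il6 by 2.47 ± 0.42. Among 15901 genes tested, 541 changed at an adjusted p under 0.05, 311 upward and 230 downward, and 188 of them changed at least 2-fold.

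Of 15 measured chemokine and colony-stimulating factor genes, 9 rose and 6 did not pass the test, while 10 rose when adjusted over the list alone (camera adjusted p = 6.0e-24). Csf2 and Csf3, which drive growth of granulocytes and macrophages, rose by 5.74 ± 0.69 and 3.95 ± 0.56 in log2 units. Csf2 started from few counts, 23 over all uninjured BALF libraries at 6 h, with 1 library at 0. Of 10 inflammatory cytokines, 5 rose and 5 did not pass (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.0e-10). Lif and Tslp were among them, at 2.52 ± 0.42 and 1.51 ± 0.25. The NF-kB group, made of pathway subunits and their feedback inhibitors, had 15 of 16 members up, and 16 adjusted over the list alone (camera adjusted p = 2.5e-54). Nfkbia and Tnip1, both inhibitors of the pathway, rose by 1.56 ± 0.17 and 1.56 ± 0.12. Birc3, an inhibitor of apoptosis, rose by 0.97 ± 0.12, and Zc3h12a, an endoribonuclease that degrades inflammatory mRNAs, from 26.3 ± 7.51 to 104 ± 17.9 CPM. A camera call given here holds with an estimated correlation unless a p with that correlation follows it. 4 of 12 leukocyte adhesion genes rose and 8 did not pass (4 adjusted over the list alone; camera adjusted p = 3.4e-10), with Icam1 at 2.73 ± 0.20 and Selp, P-selectin, at 2.38 ± 0.32.

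Innate defence genes moved in part. Lcn2, which binds bacterial iron carriers, rose by 3.40 ± 0.74, Ptx3, a soluble pattern recognition protein, by 2.87 ± 0.53, and Saa3, an acute phase protein, by 2.64 ± 0.53. 5 of 15 genes of this list rose and 10 did not pass (6 adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.19 with an estimated correlation). Of 23 interferon-stimulated genes, 3 rose, Cxcl10 by 3.20 ± 0.41 and Gbp2 by 1.91 ± 0.25, and 20 did not pass (8 rose adjusted over the list alone; camera adjusted p = 4.5e-10, adjusted p = 0.19 with an estimated correlation). 3 of 20 matrix proteases and inhibitors rose, among them the metalloproteinases Mmp9 (2.98 ± 0.44) and Mmp13 (2.50 ± 0.42), and 17 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.073). Vegfc, a lymphatic growth factor, and Pdgfb, a ligand of PDGFRβ, rose by 1.47 ± 0.20 and 2.58 ± 0.41, and 4 of 19 growth factor genes did so (6 adjusted over the list alone; camera adjusted p = 8.2e-05). Mt2, a metallothionein, and Cebpd, a transcription factor, rose by 1.79 ± 0.26 and 1.71 ± 0.25 within the glucocorticoid target list, in which 5 of 12 rose, 1 fell and 6 did not pass (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.8e-05).

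Cholesterol synthesis genes were lower in injured than in uninjured BALF at 6 h: 11 of 20 fell and 9 did not pass (15 fell adjusted over the list alone; camera adjusted p = 4.6e-20). Pmvk, phosphomevalonate kinase, stood at -1.76 ± 0.23 and Msmo1, a sterol oxidase, at -0.83 ± 0.13 on the log2 scale, and Insig1, a sterol sensor, at -0.67 ± 0.12. In the oxidative stress list, 6 of 16 genes fell, 1 rose and 9 did not pass (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.1e-07, adjusted p = 0.14 with an estimated correlation). Srxn1, sulfiredoxin, and Gsr, glutathione reductase, fell, at -1.33 ± 0.32 and -0.63 ± 0.14, while Sod2, the mitochondrial superoxide dismutase and a known NF-kB target, rose by 0.95 ± 0.13. Collagen and matrix genes showed no call in either direction (0 rose and 0 fell of 20, and none did adjusted over the list alone, edgeR; camera adjusted p = 0.52), and neither did the 16 smooth muscle contractile genes (camera adjusted p = 0.14). Neutrophil markers were 3.16 ± 0.995 CPM in injured and 1.99 ± 0.579 CPM in uninjured BALF at 6 h, and 0 of their 4 measured genes rose. With the libraries numbered 1 and 2 summed, 105 genes changed, and 24 of the 34 called genes named for this comparison kept their call, Gsr, Il6, Insig1, Klf4, Lcn2, Msmo1, Pdgfb, Ptx3, Saa3 and Srxn1 losing it. Without all libraries numbered 1 the count was 83, and without those numbered 2 it was 70; Srxn1 lost its call without any 1 of 4 single libraries, all of injured BALF and numbered 1 or 2.

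At 24 h the recruitment genes were still higher in injured BALF, and a few matrix and contractile genes were lower. Saa3 reached 231 ± 109 CPM in injured against 11.5 ± 17.9 in uninjured BALF (mean ± SD, n = 6 each), a log2 fold change of 5.08 ± 0.57 (edgeR adjusted p = 3.8e-06). Female uninjured BALF replicates 2 and 1 held 46.5 and 14.8 CPM of it, and the other uninjured BALF libraries 1.36 to 2.46. Lcn2 rose by 4.65 ± 0.70, Nos2 by 7.17 ± 0.73 and Cxcl2 by 4.26 ± 0.50. Eln, elastin, was lower in injured BALF, at 19.1 ± 10.5 against 146 ± 119 CPM, a log2 fold change of -2.92 ± 0.73 (edgeR adjusted p = 0.019), and Itga8, an integrin subunit of contractile stromal cells, stood at -1.51 ± 0.40. In all, 704 genes changed, 380 upward and 324 downward, and 253 of them at least 2-fold.

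10 of 15 chemokine genes rose and 5 did not pass (12 adjusted over the list alone; camera adjusted p = 4.1e-22), with Ccl2 at 3.07 ± 0.39 and Csf3 at 3.68 ± 0.57. 12 of 16 NF-kB genes rose (16 adjusted over the list alone; camera adjusted p = 3.3e-33), Nfkbia by 1.55 ± 0.17. Il1a and Il6 were among the 4 of 10 cytokines that rose, at 4.03 ± 0.75 and 2.06 ± 0.42 (5 adjusted over the list alone; camera adjusted p = 1.8e-05). Selp and Vcam1 were among 4 of 12 adhesion genes that rose, at 2.26 ± 0.32 and 1.04 ± 0.15 (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 5.6e-05). The acute phase list had 7 of 15 members up (9 adjusted over the list alone; camera adjusted p = 1.2e-09, adjusted p = 0.13 with an estimated correlation), and Cp, the copper carrier ceruloplasmin, rose by 2.33 ± 0.41. Within the glucocorticoid target list, 4 rose and 1 fell of 12 (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.9e-04, adjusted p = 0.068 with an estimated correlation), and Angptl4, an inhibitor of lipoprotein lipase, rose by 1.91 ± 0.19. Camp, an antimicrobial peptide stored by neutrophils, and Mmp8, the neutrophil collagenase, rose by 2.71 ± 0.69 and 1.30 ± 0.31 and made up the 2 of 4 measured neutrophil markers that rose (3 adjusted over the list alone; camera adjusted p = 3.8e-04). These markers summed to 8.60 ± 1.48 CPM in injured and 3.52 ± 2.22 CPM in uninjured BALF, and Mmp8 is also in the protease list. In the 6 uninjured BALF libraries together Camp had 18 counts and Il1a 60, each with 1 library at 0, so their fold changes start from few counts. In female uninjured BALF replicates 1 and 2, Ccl2 stood at 157 and 421 CPM, against 32.9 to 72.2 in the other 4 libraries.

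Several genes of the contractile and pericyte programme were lower in injured BALF at 24 h. Cd248, endosialin, Mcam and the transcription factor Ebf1 stood at -1.04 ± 0.21, -1.19 ± 0.32 and -0.55 ± 0.15, so that 3 of 15 pericyte markers fell and 12 did not pass (3 fell adjusted over the list alone; camera adjusted p = 3.9e-04, adjusted p = 0.068 with an estimated correlation). Male injured BALF replicate 3 had the least pericyte markers, 894 CPM summed against 991 to 1644 in the other 5 and 1344 to 2105 in uninjured BALF. It held 191 CPM of mesothelial markers against 26.1 to 73.6. Its counterpart, male uninjured BALF replicate 3 of a differing description number, held 25.2 CPM, against 37.9 to 98.0 in the other uninjured BALF libraries. At 6 h male replicate 3 held 230 CPM in injured and 262 CPM in uninjured BALF. Without male injured BALF 24 h replicate 3, Ebf1 had an adjusted p of 0.12 (edgeR). Tpm2, a tropomyosin, Mylk, myosin light chain kinase, and Actg2 fell, at -0.51 ± 0.11, -0.70 ± 0.20 and -0.81 ± 0.24, as 3 of 16 contractile genes did (10 adjusted over the list alone; camera adjusted p = 7.4e-08, adjusted p = 0.13 with an estimated correlation). Acta2, smooth muscle actin, did not pass, at -0.49 ± 0.18 (edgeR adjusted p = 0.12). In the collagen and matrix list 4 of 20 fell, Col6a3 at -0.89 ± 0.19 and Col5a1 at -0.67 ± 0.16 among them, and 1 rose, which was Dcn, decorin, by 1.37 ± 0.26 (4 fell and 2 rose adjusted over the list alone; camera adjusted p = 6.9e-04, adjusted p = 0.36 with an estimated correlation). Among proteases and inhibitors 5 rose and 3 fell of 20 (9 and 5 adjusted over the list alone; camera adjusted p = 0.23), with Mmp13 up by 2.70 ± 0.42 and Timp3, a metalloproteinase inhibitor, down, at -1.13 ± 0.18. 1 of 20 cholesterol synthesis genes fell (11 adjusted over the list alone; camera adjusted p = 7.9e-08, adjusted p = 0.19 with an estimated correlation). With libraries 1 and 2 summed the count of changed genes was 170 (124 with numbers 2 and 3 summed in female uninjured BALF instead) and 16 of the 33 called genes named for this comparison kept their call, while Actg2, Camp, Col5a1, Col6a3, Dcn, Ebf1, Eln, Il1a, Il6, Itga8, Limch1, Mcam, Mmp8, Mylk, Tgfb2, Tgfb3 and Tpm2 lost it; the count was 92 without libraries numbered 1, 129 without those numbered 2, and 416 when only the 4 groups compared were fitted. Leaving out male injured BALF replicate 3 gave 466, female uninjured BALF replicate 3 gave 327 and male uninjured BALF replicate 1 gave 413. Single libraries left out also ended calls, for this many of the 12 libraries: Actg2 (10), Camp (3), Col5a1 (1), Ebf1 (8), Eln (4), Itga8 (5), Mcam (8), Mmp8 (1), Mylk (9) and Tgfb3 (1); without female uninjured BALF 24 h replicate 3, Eln had an adjusted p of 0.10, and Acta2 passed, at 0.018, without female uninjured BALF replicate 1.

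**Figure D2:**
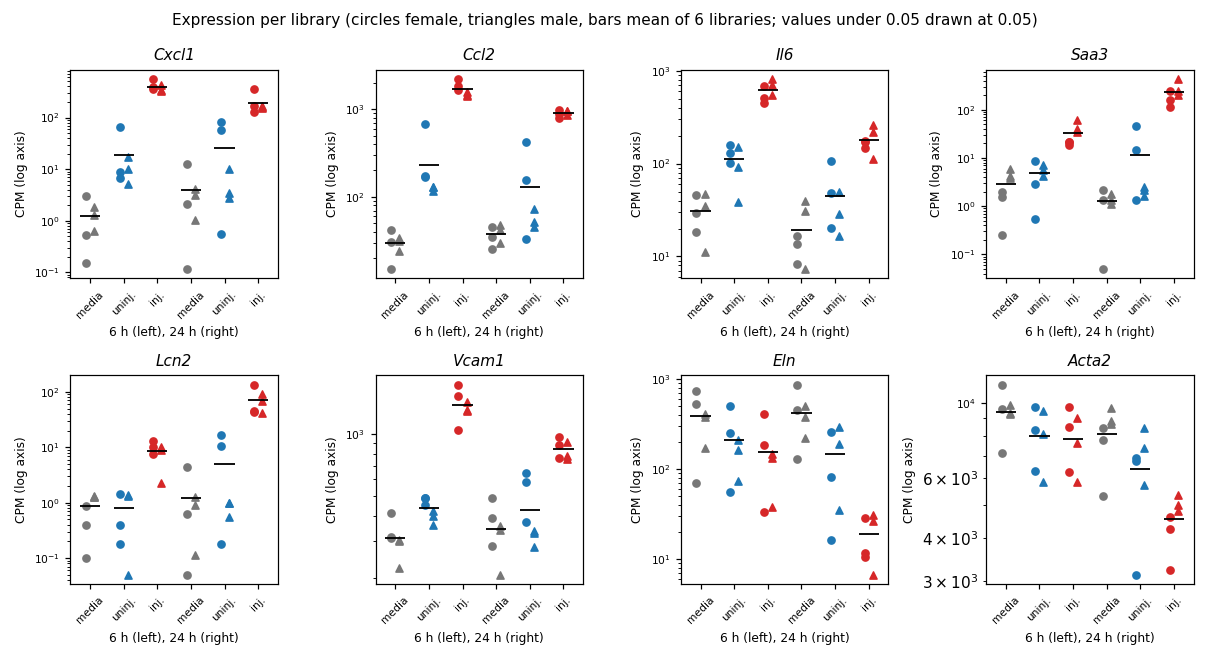
CPM of 8 genes in each library on log axes, by treatment and time; circles are female, triangles male, and bars the mean of 6 libraries. Vcam1 stands at 1384 ± 231 CPM in injured and 434 ± 50.9 CPM in uninjured BALF at 6 h (mean ± SD, n = 6).

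The genes higher in injured than in uninjured BALF overlapped between the times. Of 311 genes higher at 6 h and 380 at 24 h, 160 were shared, where independent lists would share 7.43. Of 230 and 324 lower genes, 39 were shared, against 4.69. The 2 times have no library in common, but 1 fit gave each gene the same estimate of spread at both times. Same-numbered libraries also tended to resemble each other across groups, so 7.43 and 4.69 are no test of chance. Icam1, an adhesion molecule, and Nrg1, neuregulin, had effects of injured BALF that fell from 6 to 24 h, with differences of -1.76 ± 0.27 and -1.42 ± 0.20 (edgeR adjusted p = 0.0024 and 0.0013). Crem, a regulator of cAMP responses, and Dgat1, which makes triglyceride, had effects that rose, by 1.48 ± 0.23 and 1.28 ± 0.21. The difference passed for 37 genes, 23 upward and 14 downward. In the oxidative stress list the difference was upward (camera adjusted p = 1.7e-22), with 1 of 16 genes passing alone and 13 adjusted over the list alone. Leaving out 1 library at a time moved the count by over 1.5 times for 17 of 24 libraries, from 7 without male uninjured BALF 24 h replicate 1 to 72 without male injured BALF 6 h replicate 3. Summing libraries 1 and 2 left 0 genes (edgeR), DESeq2 gave 104, and leaving out libraries numbered 1, 2 or 3 gave 0, 0 and 236; the edgeR test had 1234 genes at an unadjusted p under 0.05.

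Uninjured BALF against media asks what lavage fluid does without injury. At 6 h it already raised inflammatory and oxidative stress genes. Cxcl3 and Cxcl2 rose by 4.99 ± 0.81 and 4.59 ± 0.71 from near zero counts in media, Ccl2 rose from 29.6 ± 9.01 to 231 ± 217 CPM (mean ± SD, n = 6), and Il11, a cytokine of the IL-6 family, rose by 3.74 ± 0.41 (edgeR adjusted p = 4.8e-07). Slc7a11, the cystine carrier that feeds glutathione synthesis, rose by 3.77 ± 0.64. Rspo2, a Wnt signal enhancer, Rarb, a retinoic acid receptor, and Cyp26b1, which degrades retinoic acid, fell, with log2 fold changes of -3.49 ± 0.52, -2.49 ± 0.33 and -2.48 ± 0.44. In all, 2918 genes changed, 1676 upward and 1242 downward, 603 of them at least 2-fold.

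In the oxidative stress list 14 of 16 genes rose (15 adjusted over the list alone; camera adjusted p = 1.7e-19). 13 of 16 NF-kB genes rose (13 adjusted over the list alone; camera adjusted p = 4.3e-17), as did 6 of 10 cytokines (6 adjusted over the list alone; camera adjusted p = 3.1e-05), with Il6 at 1.84 ± 0.41. Of 15 chemokine genes 6 rose (7 adjusted over the list alone; camera adjusted p = 9.2e-05, adjusted p = 0.12 with an estimated correlation). 7 of 12 glucocorticoid targets rose (8 adjusted over the list alone; camera adjusted p = 9.1e-07). Among hypoxia response genes 8 fell and 2 rose of 16 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0064, adjusted p = 0.68 with an estimated correlation). Pdgfrb fell, at -0.58 ± 0.16. Upper-quartile scaling moved the split to 1343 higher and 1630 lower. The count was 1595 with libraries 1 and 2 summed, 1261 without number 1 and 938 without number 2, and 10 of the 11 called genes named for this comparison kept their call when summed, Pdgfrb being the exception.

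By 24 h in uninjured BALF, sterol synthesis genes stood out against media. 15 of 20 cholesterol synthesis genes rose and 5 did not pass (20 rose adjusted over the list alone; camera adjusted p = 3.1e-61). Angptl4 rose from 28.2 ± 5.80 to 118 ± 67.2 CPM (mean ± SD, n = 6), by 1.96 ± 0.19 (edgeR adjusted p = 1.4e-06), and 5 of 12 glucocorticoid targets rose (9 adjusted over the list alone; camera adjusted p = 1.4e-16). Bdkrb1, the kinin receptor induced by inflammation, rose by 1.69 ± 0.33, Ccl2 by 1.51 ± 0.37, and Fmod, the matrix protein fibromodulin, fell, at -1.55 ± 0.35. Prl2c2 was 3.08 ± 0.53, a value held as uncertain because near-identical copies of this gene may share reads. Pericyte markers lay lower as a list (camera adjusted p = 2.2e-05), though 0 of 15 passed alone and 3 adjusted over the list alone. Summed, they stood at 2891 and 2792 CPM in female media replicates 1 and 3, at 1875 to 2149 in the other 4 media libraries and at 1344 to 2105 in uninjured BALF. The count of changed genes was 138, 82 upward and 56 downward, with 41 at least 2-fold. It was 9 with numbers 2 and 3 of female uninjured BALF and 1 and 2 of the rest summed, and 5 with libraries 1 and 2 summed, where 1 of the 5 called genes named for this comparison kept their call (Angptl4), 48 without the 4 libraries of differing description numbers, and 5, 0 and 510 without numbers 1, 2 and 3. DESeq2 gave 285 genes, a fit of the 4 groups alone 28, a fit with no low-count filter 86, and leaving out male media 24 h replicate 1 gave 75, male media 24 h replicate 3 gave 76, female uninjured BALF 24 h replicate 2 gave 62, male uninjured BALF 24 h replicate 2 gave 74, male uninjured BALF 24 h replicate 3 gave 72. Ccl2 lost its call without any 1 of 11 of the 12 libraries, and Fmod without any 1 of 7. Both sums join numbers 1 and 2 of female media, which lay at a biological coefficient of variation of 36.8%. They may therefore drop a separate library.

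Injured BALF against media gave larger counts than the other treatment comparisons at both times. At 6 h Cxcl1 rose by 8.25 ± 0.95, from 1.25 ± 1.07 to 399 ± 85.4 CPM (mean ± SD, n = 6; edgeR adjusted p = 3.2e-07), Ccl2 by 5.81 ± 0.45 and Il6 by 4.31 ± 0.46. All 16 measured NF-kB genes rose (16 adjusted over the list alone; camera adjusted p = 1.2e-54), with 13 of 15 chemokine genes (13 adjusted over the list alone; camera adjusted p = 3.8e-15) and 8 of 10 cytokines (9 adjusted over the list alone; camera adjusted p = 3.0e-12). Among toll-like and cytokine receptors, which sense microbes and cytokines, 10 of 16 rose (10 adjusted over the list alone; camera adjusted p = 3.7e-05, adjusted p = 0.14 with an estimated correlation). 6 of 15 pericyte markers fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.039, adjusted p = 0.37 with an estimated correlation), with Pdgfrb at -0.70 ± 0.16. Male injured BALF replicate 3 had the least of these markers, 1019 CPM summed against 1487 to 1691 in the other 5 and 1739 to 2435 in media. It held 230 CPM of mesothelial markers against 30.4 to 76.6. Male media replicate 3, of a differing description number, had 19.9 against 45.8 to 108 CPM of the latter. Rspo2 fell, at -3.27 ± 0.52, as did Adra1d, an adrenergic receptor, at -2.71 ± 0.36. Changed genes numbered 4002, 2197 higher and 1805 lower, 971 of them at least 2-fold; upper-quartile scaling gave 1778 higher and 2276 lower. Summing libraries 1 and 2 gave 2747, and leaving out number 2 gave 1935. Without the 4 libraries of differing description numbers the count was 3300.

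At 24 h against media, Nos2 had 14015 counts in the 6 injured BALF libraries together and 2 in the 6 media libraries, a depth-corrected ratio of 6490 (95% interval 1800 to 53600, counting error only). In female injured BALF replicate 3 Nos2 reached 271 CPM, against 17.5 to 52.6 in the other 5. Saa3 rose by 7.39 ± 0.65 (edgeR adjusted p = 1.3e-08). Eln fell by 4.47 ± 0.78 on the log2 scale and Aspn, asporin, by 3.93 ± 0.68, both matrix proteins of fibroblast-like cells. Contractile genes were lower: 13 of 16 fell (14 adjusted over the list alone; camera adjusted p = 5.4e-09, adjusted p = 0.092 with an estimated correlation), with Acta2 at -0.83 ± 0.18. 7 of 15 pericyte markers fell (10 adjusted over the list alone; camera adjusted p = 5.7e-06), Cspg4, the proteoglycan NG2, at -1.11 ± 0.36 and Pdgfrb at -0.65 ± 0.16. Summed, these markers lay at 894 CPM in male injured BALF replicate 3, the library high in mesothelial markers, and at 991 to 1644 in the other 5. In media they lay at 2891 and 2792 CPM in female replicates 1 and 3 and at 1875 to 2149 in the other 4. The collagen and matrix list had 9 of 20 down and 2 up (12 and 2 adjusted over the list alone; camera adjusted p = 3.2e-05, adjusted p = 0.20 with an estimated correlation). DNA replication genes of S phase rose in 9 of 20 cases (13 adjusted over the list alone; camera adjusted p = 6.9e-05, adjusted p = 0.46 with an estimated correlation), while Mki67, a marker of cycling cells, lay at 243 ± 36.7 CPM against 243 ± 59.2 in media (adjusted p = 1.0). 13 of 16 oxidative stress genes (13 adjusted over the list alone; camera adjusted p = 2.8e-11, adjusted p = 0.057 with an estimated correlation) and 11 of 20 cholesterol synthesis genes (12 adjusted over the list alone; camera adjusted p = 7.3e-07, adjusted p = 0.20 with an estimated correlation) rose. Neutrophil markers rose in 3 of 4 cases (3 adjusted over the list alone; camera adjusted p = 8.4e-04), from 1.63 ± 0.818 to 8.60 ± 1.48 CPM summed. Changed genes numbered 3759, 1828 higher and 1931 lower, 1099 of them at least 2-fold. Without the 4 libraries of differing description numbers the count was 2937. With libraries 1 and 2 summed the count was 2120, with only the 4 groups compared 2412, and without numbers 1 and 2 in turn 1874 and 1330; Cspg4 and Pdgfrb lost their calls when summed, and Cspg4 also without any 1 of 4 of 12 single libraries.

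**Figure D3:**
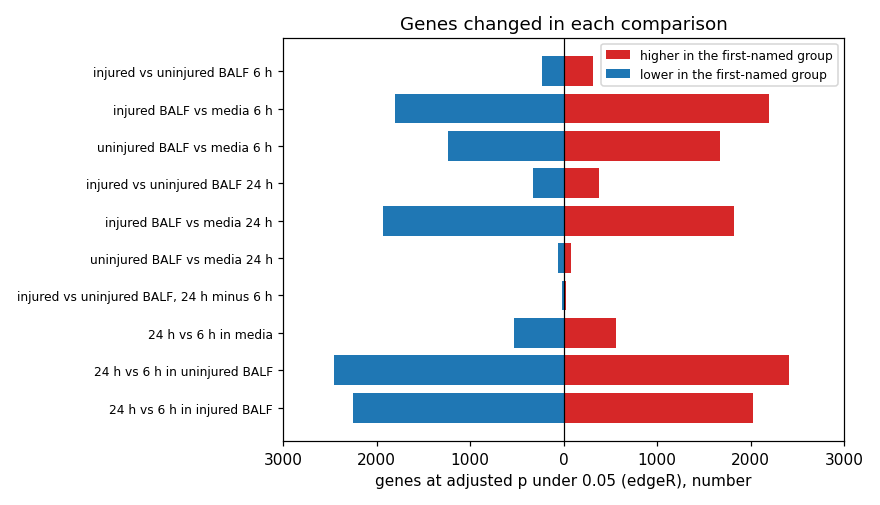
Number of genes changed in each comparison (edgeR, adjusted p under 0.05); bars to the right count genes higher in the first-named group and bars to the left genes lower. Injured BALF against media has 4002 genes at 6 h and 3759 at 24 h, and uninjured BALF against media 2918 and 138.

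Between 6 and 24 h, Cxcl2 and Il6 fell in injured BALF, and sterol synthesis genes rose in both kinds of BALF. In injured BALF Cxcl2 fell from 66.0 ± 24.0 to 6.92 ± 0.907 CPM (mean ± SD, n = 6), a log2 fold change of -3.24 ± 0.39 (edgeR adjusted p = 9.6e-07), and Il6 fell, at -1.78 ± 0.41, while Saa3 and Lcn2 rose by 2.89 ± 0.51 and 3.06 ± 0.63. 7 of 10 cytokines fell in injured BALF (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.5e-05), and 6 of 12 adhesion genes (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0018). All 20 cholesterol synthesis genes rose in injured BALF (20 adjusted over the list alone; camera adjusted p = 7.6e-45) and 18 of 20 in uninjured BALF (19 adjusted over the list alone; camera adjusted p = 9.8e-31). Glycolysis genes rose in 14 of 16 cases in injured BALF (14 adjusted over the list alone; camera adjusted p = 1.3e-10, adjusted p = 0.12 with an estimated correlation). Acta2 fell in injured BALF, at -0.79 ± 0.18, and Cspg4 in both, at -2.43 ± 0.38 in injured and -1.51 ± 0.37 in uninjured BALF. Cspg4 also tended lower with time in media, at 64.1 to 192 CPM at 6 h and 33.4 to 112 CPM at 24 h. Rarb and Dhrs3, a retinal reductase, rose in uninjured BALF by 3.04 ± 0.33 and 2.78 ± 0.33, and Il11 fell, at -4.13 ± 0.42. Has2, which makes hyaluronan, fell in media, at -1.84 ± 0.38.

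1085 genes changed with time in media, 556 higher and 529 lower at 24 h, 4864 in uninjured BALF (2407 and 2457), and 4284 in injured BALF (2026 and 2258). Upper-quartile scaling gave 3101 higher and 1895 lower in uninjured BALF and 2452 and 1802 in injured BALF. With libraries 1 and 2 summed the counts were 9, 3275 and 2891, without number 1 they were 5, 1934 and 2432, and without number 2 they were 0, 2899 and 2031. When summed, Has2 lost its call in media and Cspg4 in uninjured BALF. Numbers 1 and 2 of female media at 24 h were not close, so the summed count of 9 may rest on joining separate libraries. The media count was 372 without the 4 libraries of differing description numbers, 1634 in DESeq2 and 526 with the media libraries fitted alone. Leaving out female media 24 h replicate 1 gave 1961, female media 6 h replicate 1 gave 543, female media 6 h replicate 2 gave 663, male media 24 h replicate 1 gave 650, male media 24 h replicate 3 gave 391, male media 6 h replicate 1 gave 511 and male media 6 h replicate 2 gave 431. Female media 24 h replicate 1 had the highest mitochondrial share of counts, 3.87%.

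Female and male cells differed at genes of the sex chromosomes and at some others. Beyond Xist and the Y-linked genes, Sp9, a transcription factor, was lower in female cells, at -4.08 ± 0.59 (edgeR adjusted p = 6.3e-05), Pde3b, a phosphodiesterase, was higher by 1.40 ± 0.37, and Vcam1 by 0.32 ± 0.09. Over all treatments and times 837 genes differed, 360 higher and 477 lower in females (18 libraries each). With libraries 1 and 2 summed the count was 263, and without number 1 it was 91. Same-numbered libraries of 1 sex tended to resemble each other across treatments and times, with 32 of 36 closest to their own number. If they share an origin, each sex has far fewer than 18 independent samples. Pde3b and Vcam1 lost their calls when summed, and Pde3b without any 1 of 6 of 36 single libraries. The effect of injured against uninjured BALF differed between the sexes for 0 genes at 6 h and 0 at 24 h in edgeR, with 110 and 147 at an unadjusted p under 0.05, and for 0 and 0 in DESeq2. Chance alone would put a share of about 0.05 of the 15901 genes there, well above 110 and 147. With number as a block 142 and 198 genes lay there. The test may therefore be too strict, for a reason that was not found, and 0 does not show that the sexes respond alike. Across genes, which are not independent replicates, female and male effects correlated at a Pearson r of 0.549 and a Spearman rho of 0.501 at 6 h, and at 0.577 and 0.553 at 24 h.

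**Figure D4:**
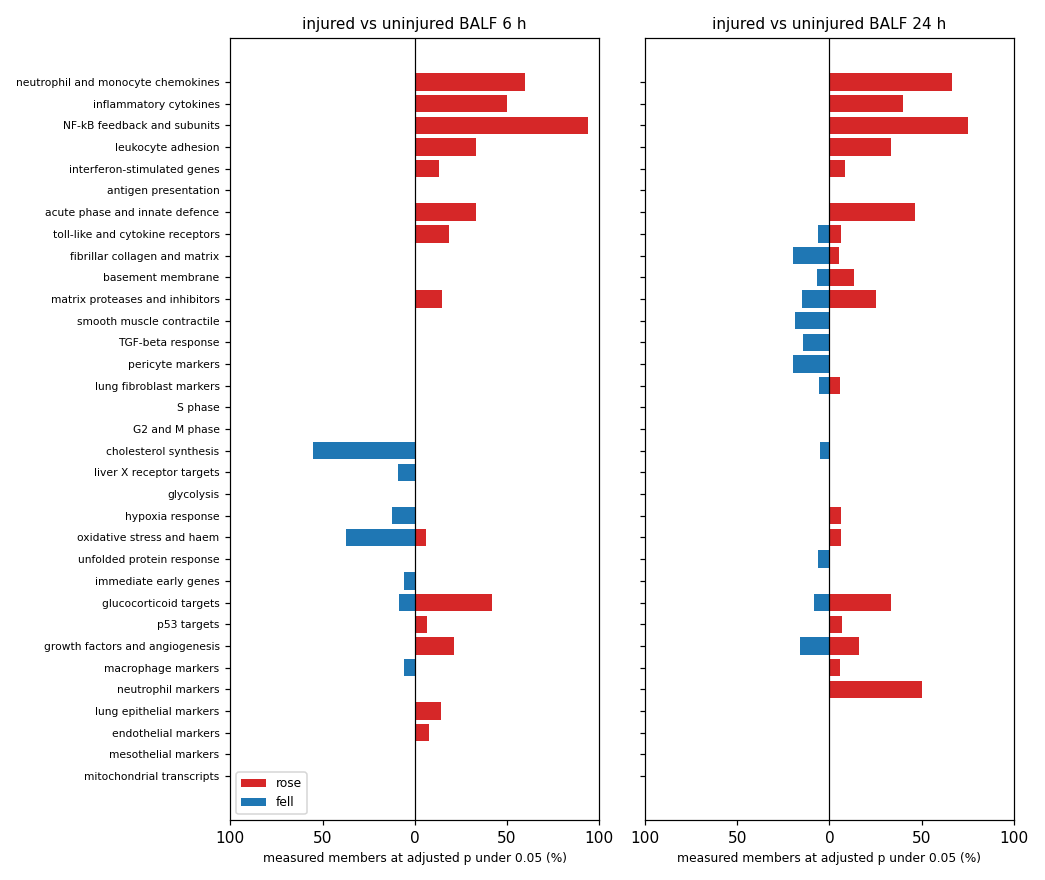
Percent of the measured genes of each list that rose (right) or fell (left) in injured against uninjured BALF at 6 h and at 24 h (edgeR, adjusted p under 0.05). NF-kB genes rose in 15 of 16 cases at 6 h and 12 of 16 at 24 h.

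On GRCm38 with the GENCODE M21 annotation, the genes that led these comparisons lie at Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938), Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688) and Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323). Counts are per gene and cover its annotated exons as the authors' counting defined them.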

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

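The tests of mixed-in material and of a wrong label were chosen only after the results were seen, and were split by library after a joint test decided nothing. In 126 sets of 6 libraries of a treatment and time, each for 1 gene or 1 summed marker list, 20 had a library far from the others, its gap to the nearest exceeding, as a share of the whole range, Dixon's 95% critical value. Chance would single out about 1 in 20 groups if their values were independent draws from 1 normal distribution. CPM of both sexes, with libraries 1 and 2 close together, are not such draws, so 20 of 126 is no measure of an excess. 15 of the 20 were libraries numbered 3, and the libraries numbered 1 and 2 of a group lay closer to each other than to number 3 in the median.

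Female injured BALF 24 h replicate 3 was high in Cxcl1 (358 CPM, nearest 166 CPM) and Nos2 (271 CPM, nearest 52.6 CPM). Female uninjured BALF 6 h replicate 3 was high in Cxcl1 (67.1 CPM, nearest 17.4 CPM) and Ccl2 (672 CPM, nearest 171 CPM). Female media 24 h replicate 3 was high in Cxcl1 (12.9 CPM, nearest 4.08 CPM). Female uninjured BALF 24 h replicate 2 was high in Ccl2 (421 CPM, nearest 157 CPM), Il6 (106 CPM, nearest 49.9 CPM) and Saa3 (46.5 CPM, nearest 14.8 CPM). Female media 24 h replicate 2 was high in Lcn2 (4.38 CPM, nearest 1.25 CPM). Female media 6 h replicate 3 was high in mesothelial markers (108 CPM, nearest 50.4 CPM) and low in Pdgfrb (556 CPM, nearest 734 CPM). Male uninjured BALF 6 h replicate 3 was high in lung epithelial markers (43.1 CPM, nearest 19.1 CPM) and mesothelial markers (262 CPM, nearest 87.2 CPM) and low in Mki67 (67.0 CPM, nearest 144 CPM). Male injured BALF 6 h replicate 3 was high in lung epithelial markers (39.0 CPM, nearest 14.6 CPM) and mesothelial markers (230 CPM, nearest 76.6 CPM) and low in pericyte markers (1020 CPM, nearest 1490 CPM). Male media 6 h replicate 3 was low in macrophage markers (18.9 CPM, nearest 64.4 CPM). Female media 24 h replicate 1 was high in lymphocyte markers (10.9 CPM, nearest 5.37 CPM). Male injured BALF 24 h replicate 3 was high in mesothelial markers (191 CPM, nearest 73.6 CPM).

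Female uninjured BALF 24 h replicates 1 and 2 had Ccl2 at 157 and 421 CPM, against 32.9 to 72.2 in the other 4 libraries. Material of an injured BALF library mixed into them would give every gene about the same share, which was read from 17 genes at least 8-fold higher in male injured than male uninjured BALF. In replicate 1 the upper quartile of the shares was 14.6 times the lower (median share 13.3%), which argues against one mixed-in share, and 16 of the 17 genes lay below the lowest injured library, which argues against a wrong label. In replicate 2 that ratio was 1.8 (median 33.4%, quartiles 25.1 to 45.2%), so mixed-in material may account for its values and stays open. Its single genes ran from 5.9% (Nos2) to 86.8% (Ccl20), and the spread that 1 share would give was not tested; the share of Nos2 is set against female injured libraries at 39.3, 17.5 and 271 CPM. In replicate 2, 12 of 17 genes lay below the lowest injured library, which argues against a wrong label. No biological explanation was tested.

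The effect of injured against uninjured BALF differed between 24 and 6 h for 37 genes in edgeR. Among those named by the rule, the effect was higher at 24 h for Procr (2.45), Nmnat2 (1.95), Pmvk (1.54), Crem (1.48) and Dgat1 (1.28), and lower for Ccl9 (-1.79), Icam1 (-1.76), Nupr1 (-1.48), Nrg1 (-1.42) and Flt1 (-1.21), in log2 units.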

How the results depend on the processing

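The sum of libraries 1 and 2, the term for the 4 libraries of differing description numbers and the tests on them were chosen after seeing the data. Each count of changed genes stayed within 1.5 times of its reported value under RLE or upper-quartile scaling, a stricter low-count filter and the term for the 4 libraries. The same held with sex ignored, which was not run for the comparisons of the sexes. Of 3241 values of 114 named-gene results under the alternatives, 2949 kept direction and side of the threshold, 289 lost the call, 3 gained it and 0 changed sign; genes given only as CPM, such as Mki67, were not followed. Depth was not varied. At the real depth, recovery was simulated for injured against uninjured BALF at 6 h alone, with libraries as separate and changed genes above 1 CPM. Of these, 43 of 50 simulated 2-fold changes and 29 of 50 of 1.5-fold were recovered. Smaller changes are therefore missed in part, and recovery of genes under 1 CPM was not tested.

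In the order used for the comparisons (injured against uninjured BALF, injured BALF against media and uninjured BALF against media at 6 h, the same at 24 h, 24 minus 6 h, time in media, uninjured and injured BALF, and sex), an adjusted p under 0.01 left 283, 2448, 1615, 294, 2145, 50, 7, 234, 3043, 2600 and 421 genes. A change of at least 2-fold as well left 188, 971, 603, 253, 1099, 41, 162, 1051, 859 and 279, without 24 minus 6 h. Both are stricter by construction. With libraries 1 and 2 summed, which leaves 2 replicates a group, the counts were 105 for injured against uninjured BALF at 6 h, 1595 for uninjured BALF against media at 6 h, 170 for injured against uninjured BALF at 24 h, 2120 for injured BALF against media at 24 h, 5 for uninjured BALF against media at 24 h, 0 for 24 minus 6 h, 9 for time in media and 263 for sex. In female uninjured BALF at 24 h, where numbers 2 and 3 were the closest pair, the numbers 1 and 3 may be crossed, so the sum was made again with these exchanged, which was chosen after seeing the data, and gave 124 for injured against uninjured BALF at 24 h, 9 for uninjured BALF against media at 24 h, 0 for 24 minus 6 h and 222 for sex (edgeR; for 24 minus 6 h 660 genes at an unadjusted p under 0.05, and 104 called by DESeq2 on all libraries). DESeq2 gave 285 for uninjured BALF against media at 24 h, 104 for 24 minus 6 h and 1634 for time in media. Fitting only the groups compared gave 416 for injured against uninjured BALF at 24 h, 2412 for injured BALF against media at 24 h, 28 for uninjured BALF against media at 24 h and 526 for time in media, no low-count filter gave 86 for uninjured BALF against media at 24 h and 609 for time in media, and leaving out the 4 libraries gave 48 for uninjured BALF against media at 24 h and 372 for time in media. Camera with an estimated correlation called 7, 6, 4, 5, 7, 3, 1, 0, 1 and 3 lists in the same order without sex. Fry called 7 for uninjured BALF against media at 24 h, 1 for 24 minus 6 h, 2 for time in media and 14 for time in uninjured BALF. The cause was not tested for these other settings.

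Leaving out single libraries or all of 1 number gave 70 to 749 for injured against uninjured BALF at 6 h, 1935 to 3703 for injured BALF against media at 6 h, 938 to 2814 for uninjured BALF against media at 6 h, 92 to 956 for injured against uninjured BALF at 24 h, 1330 to 4070 for injured BALF against media at 24 h, 0 to 510 for uninjured BALF against media at 24 h, 0 to 236 for 24 minus 6 h, 0 to 1961 for time in media, 1934 to 5111 for time in uninjured BALF, 2031 to 4352 for time in injured BALF, 91 to 1136 for sex and 0 to 2 for sex difference at 24 h. The lowest were 0 by edgeR without libraries numbered 2 for uninjured BALF against media at 24 h (888 genes at an unadjusted p under 0.05; DESeq2 on all libraries 285), for time in media (2277; 1634), and for 24 minus 6 h (870 without number 1 and 594 without number 2; 104). Summing libraries 1 and 2 left 791 at an unadjusted p under 0.05 there. The cause was not tested, beyond that fewer libraries were fitted.

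With a replicate block of number the counts were 234 for uninjured BALF against media at 24 h, 64 for 24 minus 6 h and 1783 for time in media. With a replicate block of sex by number they were 1058 for injured against uninjured BALF at 24 h, 268 for uninjured BALF against media at 24 h, 68 for 24 minus 6 h and 1765 for time in media. Camera with the replicate block called 14 for time in uninjured BALF. The libraries share only a number: 32 of 36 lay closest to their own number, a hint from the data, and correlations of same-numbered libraries ran from -0.49 to 0.65. The cause of these moves was not tested.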

Other observations

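The tests of the 4 libraries of differing description numbers, and of other splits for injured against uninjured BALF at 6 h, were chosen only after the results were seen, where a first, smaller draw of splits was raised to 100. Fas, a death receptor and the leading gene of the p53 target list, rose in injured against uninjured BALF by 1.69 ± 0.16 at 6 h and 0.71 ± 0.16 at 24 h (edgeR adjusted p = 8.3e-08 and 0.0069, n = 6). The rise of this single gene is no result for that list. Klf4, a transcription factor of vascular cells, fell at 6 h, at -0.80 ± 0.14, and Tgfb2 and Tgfb3, TGF-beta ligands, fell at 24 h, at -0.88 ± 0.20 and -1.03 ± 0.23. Limch1, an actin-binding protein of the lung fibroblast list, fell at 24 h, at -1.83 ± 0.35, and Plin2, which coats lipid droplets, rose by 0.85 ± 0.17. With libraries 1 and 2 summed, Klf4, Tgfb2, Tgfb3 and Limch1 lost their calls, as did Fas at 24 h with numbers 2 and 3 summed in female uninjured BALF.

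With time in injured BALF, 10 of 16 hypoxia response genes rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 4.8e-11, adjusted p = 0.063 with an estimated correlation). 11 of 20 G2 and M phase genes rose (19 adjusted over the list alone; camera adjusted p = 9.7e-07, adjusted p = 0.50 with an estimated correlation), and 9 of 14 TGF-beta response genes fell (10 fell and 1 rose adjusted over the list alone; camera adjusted p = 5.8e-04, adjusted p = 0.29 with an estimated correlation). Liver X receptor targets, genes of cholesterol export and lipogenesis, rose in 6 of 11 cases (7 adjusted over the list alone; camera adjusted p = 5.8e-04, adjusted p = 0.063 with an estimated correlation). Macrophage markers rose in 5 of 18 cases in injured BALF against media at 24 h (5 adjusted over the list alone; camera adjusted p = 3.1e-04, adjusted p = 0.38 with an estimated correlation), and summed to 86.5 ± 8.73 against 48.5 ± 23.3 CPM (mean ± SD, n = 6). The 2 media libraries of differing description numbers lay at 19.4 and 21.7 CPM and the other 4 at 46.4 to 72.7, against 75.1 to 97.3 in injured BALF, and without such libraries the list did not pass (camera adjusted p = 0.067). Scgb1a1, a secretory protein of airway club cells, had 40 and 25 counts in the 6 injured BALF libraries together at 6 and 24 h and 4 and 57 in uninjured BALF. It had 0 in the 12 media libraries, which allows up to 3 counts in each set of 6.

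Uninjured BALF changed 2918 genes against media at 6 h and 138 at 24 h, and the counts at 24 h ran from 0 to 510 with libraries left out. Of 975 genes called at 6 h in male libraries alone, the median change in female libraries, in the male direction, was 0.63 at 6 h and 0.25 at 24 h in log2 units, with 802 in the same direction. A larger spread at 24 h that hides unchanged effects would need at least 0.315, and with 1 library left out the median ran from 0.19 to 0.28, which argues against it. The 4 libraries of differing description numbers, 3 of them in the comparison at 24 h, may lower its count: a term for them gave 174 genes, above 138 but by less than 1.5 times, and leaving them out gave 48 with fewer libraries. That explanation stays open, as does a response to uninjured BALF that fades by 24 h, and the difference between the times was not tested gene by gene.

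Rarb and Cyp26b1, genes of retinoic acid signalling, fell in uninjured BALF against media at 6 h, as did Dhrs3, at -2.12 ± 0.33. Lower retinoic acid signalling would lower other targets too, and 9 measured targets not yet looked at, listed beforehand, had a median log2 fold change of -0.02 (camera p = 0.833 with an estimated correlation), 1 rising and 1 falling. The limit set beforehand, a median above -0.1, took no account of members that move both ways: the 95% interval of the median ran from -0.48 to 0.42. The test therefore decides nothing, and lower retinoic acid signalling stays open.

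Other splits of the same libraries were drawn for each comparison, 100 with the real split included, and shuffled within sex and time or within treatment. Taking the libraries as separate, chance as the reason for the count can be excluded for injured against uninjured BALF at 6 h (541 against 117), injured BALF against media at 6 h (4002 against 940), uninjured BALF against media at 6 h (2918 against 845), injured against uninjured BALF at 24 h (704 against 457), injured BALF against media at 24 h (3759 against 2847), time in uninjured BALF (4864 against 1801) and time in injured BALF (4284 against 1532), each with the real count and the highest of the other splits in brackets. The real split alone (1 of 100) gave as many. The same held for sex (837 against 1), but sex was shuffled separately in each treatment and time. That breaks up same-numbered libraries of 1 sex, so these splits decide nothing for sex if such libraries share an origin. As many came from 4 of 100 splits for uninjured BALF against media at 24 h (138 against 2523), 3 of 100 splits for 24 minus 6 h (37 against 234) and 2 of 100 splits for time in media (1085 against 2868). With libraries 1 and 2 summed these edgeR counts were 5, 0 (791 at an unadjusted p under 0.05, and 104 called by DESeq2 on all libraries) and 9. Chance is therefore not excluded for uninjured BALF against media at 24 h or for time in media. Even with the libraries taken as separate, other splits reached these counts, and the highest called several times as many genes. For 24 minus 6 h, treatments were exchanged within each time, which also breaks up the effects of injured BALF that both times share. Those splits therefore cannot say whether the difference between the times exceeds chance. Splits that keep libraries 1 and 2 together number 8 for a comparison of treatments or times, too few for a share under 0.05. For the sex difference of the injured against uninjured effect, edgeR called 0 genes at 6 h and 0 at 24 h (110 and 147 at an unadjusted p under 0.05, and 0 and 0 called by DESeq2), counts that all 100 splits reach whatever the data, so the splits decide nothing there (highest 31 and 115). Other splits called several times the real count for uninjured BALF against media at 24 h and for time in media, which points to a structure of the samples. In time in media the split with 2868 genes held 0 of the 4 libraries numbered 3 and 0 of the 3 of differing description numbers on 1 side, so that it followed both numbers; the count was 372 without all 4 libraries of such numbers and 1783 with number as a block. In uninjured BALF against media at 24 h the split with 2523 genes held 1 of 4 and 0 of 3, and the 2 counts were 48 and 234.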
